A study of Mus musculus with 8 samples.

How the data were processed

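Satellite cells from hindlimb muscle of C57BL/6J mice aged 3 to 4 months were profiled in 8 samples, 4 transduced with eGFP and 4 with Hoxa9 and eGFP. Per the labels' protocols, sorted cells were cultured overnight, transduced with lentiviral particles and sorted for eGFP 5 days later, and 0.1 ug of RNA was amplified and labelled with Cy3 by a low-input kit. The arrays were Agilent mouse 8x60K, 1 colour.

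The intensity values are the deposited scanner output of each array. Per the file headers and the submitters' processing notes, the authors made them with Agilent Feature Extraction 10.7.3.1, which subtracted the background and detrended each array, without scaling between arrays. The file headers give mm9 as the genome build of the probe positions, and no annotation of that build was used here. The other deposited table of processed values lacked the decimal point in 86.1% to 87.3% of its cells. With the point put back after the first digit, its columns had medians of -3.36, -3.23, -3.11 and -3.08 for the eGFP arrays and -3.24, -3.26, -3.22 and -2.95 for the Hoxa9 arrays. At least 99.89% of probes on each array lay within 0.05 of the log2 scanner value plus a constant per array. These deposited values are thus log2 signals shifted by array, with no centring by gene, and served only as an alternative.

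The processed signal was taken to log2. Each array's 75th percentile over non-control probes was subtracted, after marked spots were left out and repeated spots averaged. Over all non-control spots the 75th percentile was 514 to 779 signal units, and no spot was saturated. Control spots and spots marked as non-uniform or population outliers were left out, which removed 180 of 55681 probes. Repeated spots of a probe were averaged. Probes well above background on at least 4 of the 8 arrays were kept (40933), and each gene was represented by its probe with the highest mean, giving 27110 genes. A gene here is a distinct name, and some are accession or clone names. Those whose probe carries a RefSeq mRNA accession were 8234 with a mean above the 75th percentile and 7571 under it. A RefSeq gene table of another assembly (GRCm38) served only to update names, and matched 27656 probes, of which 1711 changed name. Among 27 named genes with several kept probes, the probes of 2, Hoxa9 and Cdkn1a, differed in sign. A gene not well above background on any array of a group has only an approximate bound there. Its fold is given as at least the bright group's mean against, per array, the higher of the probe's own signal and the lowest signal well above background. That lowest signal is taken over all probes of the array, and some probes above it were not well above background. A fold given as at least a value could thus be too large.

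Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05), with group as the only term. The 26 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The design, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. Named genes are Hoxa9, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap (leaving out accession and clone names), up to 3 members of lowest adjusted p from each list with a called member, and Pax7, Myod1, Myog, Cdkn1a and Cdkn2a. Of the genes this rule takes, 1 was left out for a reason unrelated to its values and is not reported here, though its list's totals include it. Further members, named as examples of a list, were chosen after their values were seen. These are Top2a, Cdkn1b, Igfbp2, Cxcl1, Hoxd10, Hoxb3, Fst, Stat3, Lgr5, Lgr6, Ifitm3, Col1a2, Pdgfra and Dcn.

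The arrays lay on 3 slides, each holding both groups: slide 1 had 2 eGFP arrays and 1 Hoxa9 array, slide 2 had 1 and 2, and slide 3 had 1 and 1. The experiment number in the titles is shared by the groups. Deviations from the group means correlated at 0.143, 0.228, 0.129 and 0.186 in the 4 same-numbered pairs. All exceeded 0.1, the limit set for pairing, so the numbers were taken to pair the samples and were used as a block in an alternative. Of the 12 unlike-numbered pairs 2 also exceeded it, Hoxa9 replicate 3 with eGFP replicate 4 (0.188, on a shared slide) and Hoxa9 replicate 4 with eGFP replicate 3 (0.137), so the check does not tell the numbers 3 and 4 apart. Pearson correlations over genes were 0.975 to 0.992 among eGFP arrays, 0.952 to 0.986 among Hoxa9 arrays and 0.931 to 0.969 between groups.

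The other alternatives were quantile normalization, a median shift, normexp background correction (offset 50), no filter or a stricter filter on dim probes, the deposited table, the mean of a gene's probes, the slide as a block, an intensity trend with a robust prior, array weights, a 2-fold minimum, and leaving out each array in turn.

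The gene and list tests were tested on simulated data for the Hoxa9 and eGFP comparison, over 27110 genes with the observed means and spread and with 200 genes changed in each of 5 runs. They recovered 0.299% of genes changed 1.5-fold, 14.6% of those changed 2-fold and 72.1% of those changed 4-fold, and 6.06% of calls were false on average. A list shifted by 0.5 was called in 5 of 5 runs. The simulated genes were independent of each other, so the simulation says nothing about correlated lists. Only 200 genes and the shifted list were changed per run, against 4100 genes called in the data. The Benjamini-Hochberg cutoff was thus stricter in the simulation, and the recovered shares do not carry over to the data.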

Results

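Gene expression was measured in cultured satellite cells, the resident stem cells of skeletal muscle, taken from hindlimb muscle of young adult C57BL/6J mice. The sorted cells were transduced with a lentivirus carrying eGFP alone (control) or Hoxa9 together with eGFP, and eGFP-positive cells were sorted again 5 days later for RNA extraction. Hoxa9 is a homeobox transcription factor that patterns the body axis and limbs in development. Each group comprised 4 one-colour Agilent arrays, numbered 1 to 4 in both groups. Each array carried 62976 spots, of which 3671 were controls, and between 69.6% and 77.5% of the non-control spots were well above background. The number of arrays limits the precision of every value given here, and the labels do not say that the 4 samples of a group came from separate animals, so p-values measure the spread between these samples. The comparison asks which transcripts differed when Hoxa9 was overexpressed in these cells. All differences are log2 values of Hoxa9 minus eGFP, with n = 4 arrays per group.

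The overexpressed gene was examined first, through its 2 probes on the array. The brighter Hoxa9 probe, at chromosome 6, 52175595 to 52175654 (mm9, minus strand), rose 62.8-fold. It read 5.49 ± 0.21 (SD, n = 4) on the log2 scale relative to the array's 75th percentile in the Hoxa9 arrays and -0.49 ± 0.44 in the eGFP arrays (log2 difference 5.97, SE 0.24, adjusted p = 1.504e-05, limma). Every Hoxa9 array, from 5.28 to 5.79, lay above every eGFP array, from -0.98 to -0.07. The other Hoxa9 probe, at chromosome 6, 52174165 to 52174224, went the opposite way. Its level was -3.46 ± 0.085 in the Hoxa9 arrays and -1.71 ± 0.18 in the eGFP arrays, a 3.35-fold lower signal (log2 difference -1.75, SE 0.16), with all 8 arrays well above background. Both probes carry the same RefSeq transcript in the files, and whether either lies in the transduced cDNA is not given in the sources used here. Averaging the 2 probes reduced the difference to 2.11. Within slides the brighter probe differed by 6.64, 5.52 and 5.52, and by 5.93 with the slide as a block.

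**Figure D1:**
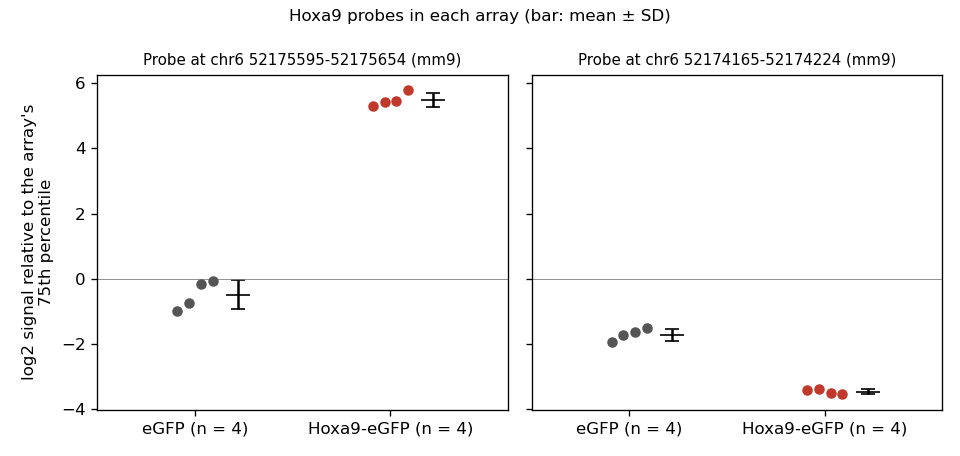
Log2 signal of each of the 2 Hoxa9 probes relative to the array's 75th percentile (vertical axis), with a point per array and the mean ± SD beside each group of 4. The left probe lies between 5.28 and 5.79 in the Hoxa9 arrays and below 0 in the eGFP arrays, whereas the right probe is lower in the Hoxa9 arrays (mean -3.46 against -1.71).

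Hoxa9 overexpression was accompanied by change in both directions across the transcriptome. Of 27110 genes tested, 2090 were higher and 2010 lower in the Hoxa9 arrays (limma, Benjamini-Hochberg adjusted p under 0.05), and 1342 of the higher and 1130 of the lower genes changed at least 2-fold. The 4 arrays of each group did not overlap in 6372 genes (23.5%), against 2.86% by chance. The median difference over all genes was -0.08. With the slide as a block 1657 genes were higher and 1394 lower. Without the eGFP array of replicate 2, 1303 genes were lower.

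The 8 genes with the largest fitted rises included 4 that were not well above background on any eGFP array, so that their size is an approximate bound and their order is not known. Iapp, which encodes the islet hormone amylin, rose at least 454-fold (adjusted p = 0.0001138), and Chrdl1, a secreted BMP antagonist, rose at least 397-fold (adjusted p = 1.739e-07). The matricellular gene Ccn3 rose at least 81.6-fold and Gcg, the glucagon precursor, at least 71.7-fold. These folds depend on the processing. Over the alternatives the smallest log2 differences were 5.73 for Iapp, 5.42 for Chrdl1, 3.38 for Ccn3 and 3.17 for Gcg. Car3, a carbonic anhydrase of muscle and fat, rose by a log2 difference of 7.04 (SE 0.39, adjusted p = 3.897e-05) and Mstn, the muscle growth inhibitor myostatin, by 6.81, with 3 eGFP arrays well above background. The extracellular chaperone gene Clu rose by 6.78 and the lipid phosphatase gene Mtmr7 by 6.75. Among the largest fitted falls, Prss46, a serine protease gene, decreased by 3.75 (SE 0.48, adjusted p = 0.001383) and the chemokine scavenger receptor Ackr4 by 3.57. Lef1, a transcription factor of the canonical Wnt pathway, decreased by 3.50 (SE 0.37, adjusted p = 0.0005715), Col2a1 by 3.50, Laptm5 by 3.49 and Nptx1 by 3.43. Col2a1 was well above background on 2 Hoxa9 arrays and Nptx1 on 3. Cyth4 was at least 4.26-fold and Itgb8 at least 5.61-fold lower, neither being well above background in any Hoxa9 array. The smallest log2 difference of Cyth4 over the alternatives was -0.58. The call for Itgb8 was lost with normexp background correction (-0.67, adjusted p = 0.0656, the highest over its alternatives, the lowest being 0.002315).

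**Figure D2:**
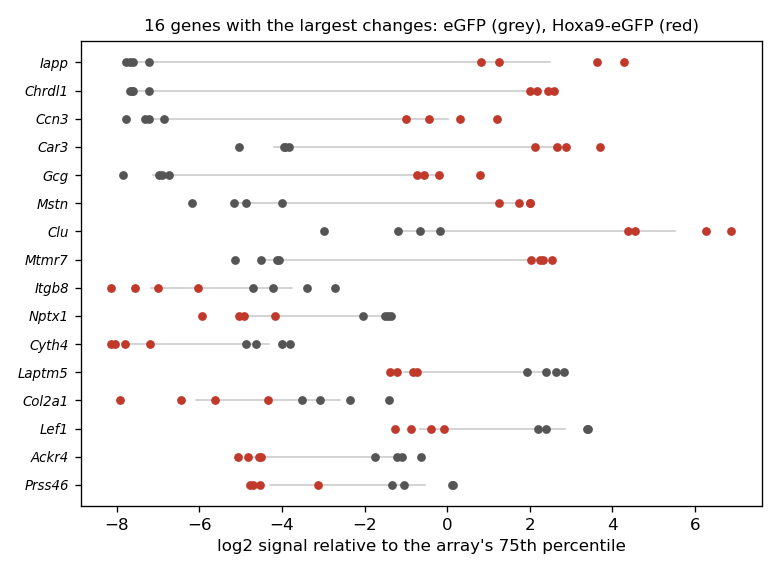
Log2 signal relative to the array's 75th percentile (horizontal axis) for the 8 genes with the largest fitted rises and the 8 with the largest fitted falls, with grey points for eGFP arrays, red points for Hoxa9 arrays and a line between the group means. The 2 groups do not overlap in any of the genes, but the eGFP points of Iapp, Chrdl1, Ccn3 and Gcg and the Hoxa9 points of Cyth4 and Itgb8 are background readings, not measured levels.

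Cell cycle genes fell together. Of 55 measured members of the cell cycle and DNA replication list, 49 were lower and 0 higher in the Hoxa9 arrays (52 and 0 adjusted over the list alone; all 55 had an unadjusted difference below 0), with a mean log2 difference of -1.52. Nusap1, a mitotic spindle protein, decreased by 1.78 (SE 0.15, adjusted p = 0.0002121), the S-phase cyclin gene Ccne1 by 1.84 and the transcription factor E2f2 by 1.55. The DNA topoisomerase gene Top2a decreased by 1.88. The list stood apart from other genes with a preset correlation between genes (camera, adjusted p = 2.151e-28). It did not with an estimated correlation (adjusted p = 0.2704). The list mean differed by -1.96, -1.48 and -0.87 within the 3 slides and by -1.49 with the slide as a block.

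Inhibitors of the cell cycle did not move as a group. Among 34 measured CDK inhibitors and p53 targets, 6 were higher and 5 lower (10 and 7 adjusted over the list alone, camera adjusted p = 0.4074). Cdkn1c, the inhibitor p57, decreased by 2.92 (SE 0.33, adjusted p = 0.0008287) and the stress-induced gene Ddit4 by 1.99. The death receptor Fas rose by 2.17 and the CDK inhibitor gene Cdkn1b by 0.87 (SE 0.16, adjusted p = 0.008674). Cdkn1a, the inhibitor p21, differed by 0.36 (SE 0.15, adjusted p = 0.1561) and Cdkn2a, which encodes p16 and Arf, by -0.61 (SE 0.19, adjusted p = 0.07033). Cdkn1a passed the threshold with quantile normalization (0.53, adjusted p = 0.02387), its highest adjusted p over the alternatives being 0.3809. Cdkn2a passed it in 3 alternatives, namely the mean of its probes, an intensity trend with a robust prior, and array weights, with an adjusted p of 0.03755 to 0.1577 over all alternatives. Of 40 measured secreted factors associated with senescence, 15 were higher and 11 lower (16 and 11 adjusted over the list alone), with a mean of 0.34, a median of -0.05 and a camera adjusted p of 0.2783. The growth factor genes Ereg (3.78, SE 0.20) and Fgf2 (2.83) and the IGF-binding protein gene Igfbp5 (3.66) rose, while Igfbp2 decreased by 2.79 and the chemokine gene Cxcl1 by 2.21. The lists of CDK inhibitors, secreted factors, Wnt, TGF-beta and JAK/STAT genes were drawn up knowing that the study discusses such pathways, and are not independent of it.

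Other Hox genes mostly fell. Of 32 measured Hox genes other than Hoxa9, 18 were lower and 2 higher (21 and 2 adjusted over the list alone), with a mean difference of -1.11. Hoxa11 decreased by 3.08 (SE 0.15, adjusted p = 3.711e-05) and Hoxd4, above background on 2 Hoxa9 arrays, by 2.78. The exceptions were Hoxd10, which rose at least 3.41-fold, and Hoxb3, which rose by 1.44. In the HoxA cluster 7 of 10 measured genes were lower and 0 higher. The list was called with a preset correlation (camera adjusted p = 6.172e-10) and with an estimated one (adjusted p = 0.01026), though not with an estimated correlation and the replicate number as a block (adjusted p = 0.0893). It differed by -0.86, -1.34 and -1.19 within slides and by -1.12 with the slide as a block. Their TALE cofactors, homeodomain proteins that bind DNA with Hox proteins, included 1 higher and 2 lower of 11 (2 and 3 adjusted over the list alone, 2 and 3 with the replicate block, camera adjusted p = 0.9003). Pknox1 rose by 1.52, Pknox2 decreased by 1.14 and Pbx3 by 0.95. Among 19 genes tied to Hoxa9 in blood cells, 2 were higher and 6 lower (3 and 6 adjusted over the list alone, 4 and 6 with the replicate block, camera adjusted p = 0.4202). Myb, a transcription factor of blood progenitors, decreased by 2.41, Camk2d by 1.74 and Id2 by 1.51. Of 41 Polycomb and Trithorax regulators, 4 were higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.9516). The histone methyltransferase genes Ezh1 and Ezh2 parted, at 1.36 and -1.73, and Cbx2 decreased by 1.24.

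Satellite cell identity genes fell more often than they rose. Of 24 measured, 8 were lower and 3 higher (11 and 4 adjusted over the list alone), with a mean of -0.38 and a camera adjusted p of 0.132. Pax7, the transcription factor that marks satellite cells, decreased by 1.31 (SE 0.21, adjusted p = 0.004058). The adhesion molecule gene Vcam1 decreased by 2.59 (SE 0.19, adjusted p = 0.00011) and Sdc3 by 1.61, while Chrdl2, well above background on 1 eGFP array, rose by 3.16. Myod1, a muscle determination factor, differed by -0.23 (SE 0.19, adjusted p = 0.4752).

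Muscle differentiation genes gave a mixed picture. Of 56 measured, 9 were higher and 3 lower (9 and 3 adjusted over the list alone), with a mean of 0.55, and 18 were higher and 7 lower with the replicate number as a block. The fast myosin gene Myh2 rose by 3.14 (SE 0.32, adjusted p = 0.0005081) and the thin-filament gene Tmod1 by 3.19, while the brain-type creatine kinase gene Ckb decreased by 1.42. Myog, which encodes the differentiation factor myogenin, differed by -0.77 (SE 0.40, adjusted p = 0.2645), and passed the threshold with the replicate block (adjusted p = 0.03635, the highest over its alternatives being 0.4622). The list was called with a preset correlation of 0.01 (camera adjusted p = 0.009181) and not with an estimated correlation, which was 0.666 (adjusted p = 0.7423). It was not called with fry either (adjusted p = 0.3713). Its camera adjusted p was 0.0568 without the eGFP array of replicate 1 and 0.07929 without the eGFP array of replicate 2. That value was 0.1021 and 0.06339 without the Hoxa9 arrays of replicates 3 and 4. It differed by 1.57, -0.24 and 0.26 within slides, so that the sign was not shared, and by 0.56 with the slide as a block. The slides mix the experiment numbers, however. Within same-numbered pairs the list was higher in the Hoxa9 array in 4 of 4, by 0.49 to 0.70. Markers of smooth muscle and of fibroblasts, in lists that were not called, ran with it over the arrays. The smooth muscle means were -0.21, -0.40, 0.18 and 0.43 in eGFP replicates 1 to 4 and 0.34, 0.18, 0.91 and 0.76 in Hoxa9 replicates 1 to 4. The fibroblast means were -0.35, -0.43, 0.47 and 0.31, and -0.02, 0.22, 1.03 and 0.84.

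**Figure D3:**
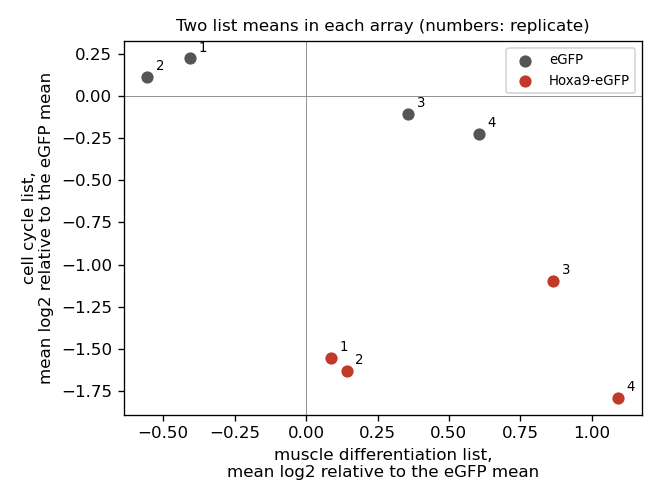
Mean of the muscle differentiation list (horizontal axis) against mean of the cell cycle list (vertical axis) in each array, both as log2 values relative to the mean of the eGFP arrays, with the replicate number beside each point. The 4 Hoxa9 arrays have cell cycle means of -1.79 to -1.10, below all eGFP arrays (-0.23 to 0.22), while the 2 groups overlap on the horizontal axis.

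TGF-beta and BMP genes rose more often than they fell. Of 66 measured, 19 were higher and 6 lower (22 and 7 adjusted over the list alone), with a mean of 0.49 and a median of 0.13. The camera adjusted p was 0.009181, against an adjusted p of 0.2704 with an estimated correlation. Besides Mstn, the ligand gene Bmp4 rose by 3.77 (SE 0.22, adjusted p = 5.001e-05) and the secreted Fstl1 by 2.28, as did Fst, which encodes the activin and myostatin antagonist follistatin, by 4.71. Both ligands and antagonists were among the rises, and 3 genes were lower without the Hoxa9 array of replicate 1. The list differed by 0.45, 0.47 and 0.48 within slides and by 0.47 with the slide as a block. Of 62 JAK/STAT genes, 16 were higher and 5 lower (18 and 5 adjusted over the list alone), with a mean of 0.25 and a median of 0.07. The camera adjusted p of this list was 0.01666, against an adjusted p of 0.4062 with an estimated correlation. The receptor gene Il11ra1 rose by 2.10 (SE 0.15, adjusted p = 0.000109) and the transcription factor Stat3 by 1.82, while the receptor gene Il4ra decreased by 1.32 and the cytokine gene Il11 by 1.58. In this list 3 genes were lower without the eGFP array of replicate 2 or 3 or the Hoxa9 array of replicate 1, 2 or 4, and its adjusted p was 0.06109 without the Hoxa9 array of replicate 3. It differed by 0.20, 0.27 and 0.36 within slides and by 0.27 with the slide as a block.

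Wnt and Notch genes moved both ways. Of 64 Wnt pathway genes, 10 were higher and 7 lower (13 and 11 adjusted over the list alone), with a mean of 0.08, a median of -0.02 and a camera adjusted p of 0.5767. The planar polarity gene Prickle1 (2.24, SE 0.19) and the R-spondin receptor genes Lgr5 (3.83) and Lgr6 (3.22), both above background on 3 eGFP arrays, rose. The ligand gene Wnt7b was lower, in addition to Lef1. Of 32 Notch pathway genes, 5 were higher and 7 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.7127). The coactivator gene Maml2 rose by 2.75 and the ligand gene Jag1 by 2.26, while the receptor gene Notch3 decreased by 2.15.

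Interferon-response genes rose as a group. Of 53 measured, 21 were higher and 1, Ifitm3 (-0.94), was lower (24 and 2 adjusted over the list alone, 21 and 2 with the replicate block), with a mean of 0.63. Ifih1, a sensor of double-stranded RNA, rose by 3.02 (SE 0.15, adjusted p = 3.897e-05), the related sensor gene Ddx58 by 1.67 and the ubiquitin ligase gene Dtx3l by 1.63. The list was called with a preset correlation (camera adjusted p = 3.708e-08) and with an estimated correlation (adjusted p = 0.00916), though not with an estimated correlation and the replicate block (adjusted p = 0.0893). It differed by 0.69, 0.54 and 0.72 within slides and by 0.64 with the slide as a block. Both groups had received lentivirus.

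Extracellular matrix genes also changed in both directions. Of 65 measured, 17 were higher and 9 lower (21 and 12 adjusted over the list alone), with a mean of 0.46. Thbs2, a matricellular protein gene, rose by 5.08 (SE 0.14, adjusted p = 2.812e-06), the metalloproteinase inhibitor gene Timp3 by 3.90 and the metalloproteinase gene Mmp2 by 3.27, while the collagen gene Col1a2 decreased by 2.50. The camera adjusted p was 0.03455, and 0.6213 with an estimated correlation. The call was also lost with normexp (0.06941), with only probes above background on all 8 arrays (0.06902), and without the eGFP arrays of replicate 1 (0.0568) or 2 (0.07783) or the Hoxa9 array of replicate 3 (0.1848). The list differed by 0.82, 0.03 and 0.63 within slides and by 0.48 with the slide as a block. Within same-numbered pairs, which the slides mix, it was higher in the Hoxa9 array in 4 of 4, by 0.24 to 0.55. The fibroblast marker list, which shares 4 genes with it and was not called, differed by 1.23, -0.37 and 0.72 within the same slides. Within the 4 same-numbered pairs that fibroblast list differed by 0.34 to 0.65. Its means ran with those of the matrix list over the arrays, at -0.35, -0.43, 0.47 and 0.31 in eGFP replicates 1 to 4 and -0.02, 0.22, 1.03 and 0.84 in Hoxa9 replicates 1 to 4, against matrix means of -0.07, -0.24, 0.19 and 0.11, and 0.17, 0.27, 0.74 and 0.66.

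Stress and survival lists were not called. Of 37 apoptosis regulators, 5 were higher and 6 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.5767). Besides Fas, the inhibitor gene Birc3 rose by 0.94, and Cycs, which encodes cytochrome c, decreased by 0.78. Birc3 lost its call with the slide as a block (adjusted p = 0.05541) and without the eGFP array of replicate 2 (0.05787) or the Hoxa9 array of replicate 1 (0.05228), its lowest adjusted p over the alternatives being 0.004074. Of 41 genes of the unfolded protein and integrated stress response, 4 were higher and 9 lower (5 and 10 adjusted over the list alone, camera adjusted p = 0.2778). Nupr1 rose by 1.77 and the cysteine synthesis gene Cth decreased by 1.86. Of 32 genes that respond to dissociation and sorting, 6 were higher and 4 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.1373). Btg2 rose by 1.44 and Fosl2 by 1.43, while Fosl1 decreased by 1.47.

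Markers of other cell types that a sort could hold were measured in the same way, and none of these lists was called in the fixed test. Of 17 fibroblast and fibro-adipogenic markers, 3 were higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.2349). Ly6a, which encodes the surface antigen Sca-1, rose by 4.55 (SE 0.48, adjusted p = 0.0005577) and Ly6c1 by 4.18, while Fbln1 decreased by 1.41. The fibroblast genes Pdgfra (-0.64, adjusted p = 0.2179) and Dcn (0.12, adjusted p = 0.9346) did not pass the threshold. Of 18 smooth muscle and pericyte markers, 6 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.2349). Mylk rose by 1.98 and Pln, a regulator of the sarcoplasmic calcium pump, at least 6.12-fold, while Notch3 was lower. The smallest log2 difference of Pln over the alternatives was 0.76. Of 13 adipocyte markers, 5 were higher and 1 lower (6 and 1 adjusted over the list alone, 6 and 0 with the replicate block, camera adjusted p = 0.07986). The lipid-binding protein gene Fabp4 rose by 3.49, the transcription factor Cebpa by 1.70 and Acsl1 by 1.42. The adipocyte list was called with a median shift (adjusted p = 0.02501) and without a filter on dim probes (adjusted p = 0.03427). Of 15 endothelial markers, 4 were higher, among them Esam (1.56, above background on 2 eGFP arrays) and Ramp2 (1.04), and 1 was lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.3833). Of 16 tendon, cartilage and bone markers, 0 were higher and 2 lower (0 and 2 adjusted over the list alone, 1 and 2 with the replicate block, camera adjusted p = 0.9516), namely Col2a1 and the tendon factor Scx, which decreased by 1.39. Of 16 leukocyte markers only Laptm5 passed the threshold, downward (0 and 1 adjusted over the list alone, camera adjusted p = 0.7054). Of 15 Schwann cell and glial markers only the neurotrophin receptor gene Ngfr passed the threshold, downward (0 and 1 adjusted over the list alone, camera adjusted p = 0.2349). None of 5 measured erythroid markers passed the threshold (0 and 0 adjusted over the list alone, camera adjusted p = 0.8078, limma).

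**Figure D4:**
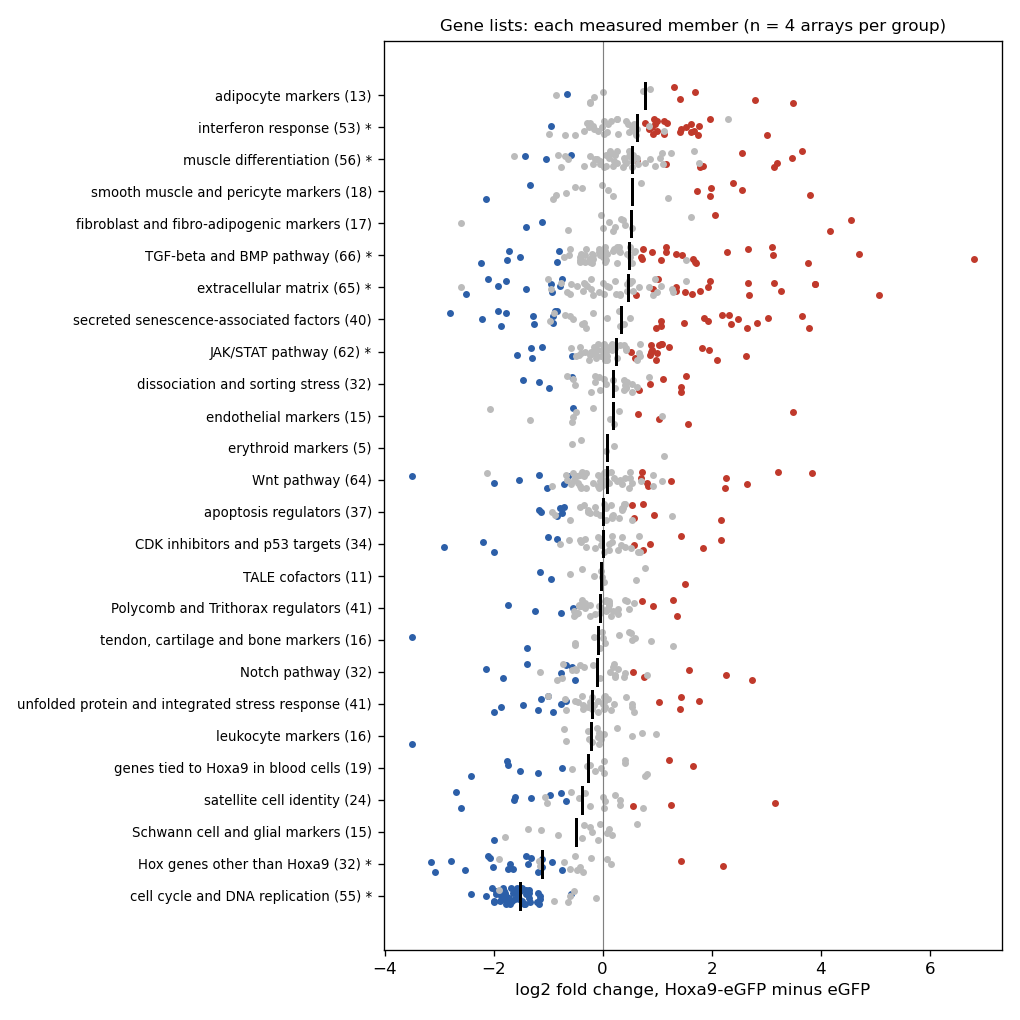
Log2 fold change of every measured member (points, horizontal axis) of the 26 gene lists (a line each, number measured in parentheses), in red for called rises, blue for called falls and grey for genes past no threshold, with a black bar at the list mean and an asterisk for the 7 lists called by camera with a preset correlation. The cell cycle list lies furthest to the left (mean -1.52).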

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

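All tests that weigh an explanation here were chosen after the results were seen. Among 222 groups of 4 arrays checked (the named genes, the list means and the share of probes above background), 9 had an array whose gap to its nearest neighbour, divided by the group's range, exceeded Dixon's critical value for 4 samples. Chance gives about 1 in 20 groups, or 11.1. In the eGFP arrays these were replicate 2 for Chrdl1 (ratio 0.870, at -7.24 against -7.68 to -7.62, all background readings) and Ddit4 (0.904, at 4.96 against 5.19 to 5.22), replicate 1 for Car3 (0.909, at -5.04 against -3.94 to -3.83), replicate 4 for Ckb (0.918, at 3.36 against 3.14 to 3.16), and replicate 3 for E2f2 (0.868, at 4.76 against 4.96 to 4.99) and Il11 (0.894, at 1.42 against 0.56 to 0.65). In the Hoxa9 arrays replicate 3 stood apart for Prss46 (0.856, at -3.12 against -4.77 to -4.53), Scx (0.843, at 4.73 against 4.27 to 4.34) and Cdkn2a (0.902, at 3.35 against 3.88 to 3.94).

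The number of called genes was not reached by other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called as many as 4100 genes, and the highest of the others called 12. That share is under 0.05, but the 35 splits leave the pairing of the samples aside. Among the 8 splits that part all 4 same-numbered pairs the highest other also called 12. These 8 splits are too few for a share under 0.05, so with the pairing kept this test cannot exclude chance. The number of gene lists called with a preset correlation was different. The real split called 7 lists, and 5 of the 35 splits, the real one included, called as many, the highest other calling 7. Each of the others that called 7 kept most arrays of each group together, and so part of the real contrast. Splits with as many arrays of each group on either side called at most 5. The ties are thus no measure of chance, and for that count this test cannot decide on it. Among the 8 splits that part all 4 pairs, again too few, the highest other called 6.

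Cell cycle genes were lower in the Hoxa9 arrays. Array scaling is argued against: relative to the median of all genes the list mean nearest 0 over quantile, median and normexp processing was -1.33 (SE 0.19). The slide is argued against as the whole source, since the smallest within-slide difference, -0.87, exceeded in size the range of 0.45 among the eGFP arrays. Further muscle differentiation of the Hoxa9 cells, which could lower cycling, could be weighed only across experiment numbers. In the 4 pairings of a Hoxa9 array with an eGFP array of higher differentiation mean, the cell cycle mean was still lower in the Hoxa9 array. The log2 difference was -1.52 to -1.32, and with the differentiation list as a covariate the group difference was -1.43 (SE 0.22). These pairings set Hoxa9 replicates 1 and 2 against eGFP replicates 3 and 4. Both lists also differed between those numbers among the eGFP arrays, the cell cycle means being 0.22 and 0.11 against -0.11 and -0.23. The pairings thus cannot separate differentiation from the experiment number. Same-numbered pairs cannot separate it from Hoxa9 (-0.84, SE 1.32, with the number as a block too). Differentiation as a part or the whole of the change, and an effect of Hoxa9 itself, stay open.

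The 2 Hoxa9 probes went opposite ways. Array scaling is argued against, since the lower probe's difference relative to the median of all genes was -1.04 (SE 0.08) at its nearest to 0 over the 3 processings. A candidate explanation is that the lower probe reads the cells' own HoxA transcripts, and that these fell: 7 of the 10 other measured HoxA genes were lower and 0 higher. The positions of the probes relative to the transduced cDNA stay open, and that reading is a hypothesis found and tested on the same data.

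The Hoxa9 array of replicate 2 stood apart, with correlations of 0.952 to 0.962 with its group against 0.978 to 0.986 among the other 3. A sample from the eGFP group under a wrong label is argued against by its level of 5.42 on the brighter Hoxa9 probe, within the range of the other Hoxa9 arrays. The slide is argued against, since the other Hoxa9 array of slide 2 correlated at 0.978 or more with those of the other slides. Noise of low-signal probes could not be settled as the source. The array's spread around the other Hoxa9 arrays was 1.68 times theirs in 15948 genes under the 75th percentile. In 11162 genes above it that spread was 1.26 times theirs and the largest of the 4, but little above that of replicate 4 (0.41 against 0.38). In the 8234 of these that are RefSeq mRNA genes (1.11 times) it was not the largest. Such noise and a true difference of that sample both stay open.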

How the results depend on the processing

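The alternatives were fixed before the data were examined, except for keeping the marked spots, the replicate block with an estimated correlation, the list counts without the Hoxa9 array of replicate 2 and the exact permutation test of list means, which were chosen after seeing the data. Requiring 2-fold left 1342 higher and 1130 lower genes, by construction. Leaving out each array in turn gave 1545 to 1873 higher genes, 1303 to 1877 lower genes and 4 to 7 called lists, and in the same settings the brighter Hoxa9 probe differed by 5.81 to 6.11. Over all other alternatives the counts stayed within 1.5 times the reported ones, and no called gene reversed in any. With the replicate block 2264 genes were higher and 2127 lower, of which 1849 and 1736 were among those reported. Among the lists and the genes named by the fixed rule, that block changed no call other than those given with their results. Without the Hoxa9 array of replicate 2 the counts were 1873 and 1877. The number of lists called was 2 with an estimated correlation, 13 with fry, which does not compare a list with other genes, 0 with the replicate block and an estimated correlation, and 0 with the exact permutation test, whose smallest p was 0.02857 in 11 of 26 lists. The cause of these differences was not tested beyond the tests' construction. A median shift moved the median of all genes to -0.10. Of 79 called named genes besides Hoxa9, 77 kept their call in all alternatives that measured them. Most were named for a low adjusted p or a large change, so that share does not carry over to all calls. With the slide as a block 1587 of the 2090 higher and 1338 of the 2010 lower genes kept their call. Uncalled lists with a mean near 0, such as TALE cofactors and apoptosis regulators, changed sign between settings. Of the 19 uncalled lists, 10 had the sign of their mean within all 3 slides. Signal over background limits genes below it, since 22.5% to 30.4% of spots were not well above background.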

Other observations

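The genes in this part were chosen after their values were seen. Among called genes, 132 were well above background on all 4 Hoxa9 arrays and no eGFP array, and 24 showed the reverse. Detection itself differed in the same direction, with 72.2% to 77.5% of probes well above background on the Hoxa9 arrays against 69.6% to 73.0% on the eGFP arrays, and a lowest such signal of 7.22 to 10.4 against 9.71 to 14.2 units. Some further genes with large changes are named singly, without a test of any group they belong to. Ghrh, the growth hormone releasing hormone, rose by 4.73 (SE 0.73, adjusted p = 0.003374), Penk, the enkephalin precursor, by 4.44 (SE 0.36, adjusted p = 0.0001749), and Prl8a2, a placental prolactin family gene, at least 9.24-fold. Gal, the galanin precursor, decreased by 3.03 (SE 0.25, adjusted p = 0.0001941). Pcsk5, a protease that processes precursor proteins, rose at least 38.0-fold.

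The homeobox genes Msx3, Nkx1-1 and Nkx1-2, which lie outside the Hox clusters, rose by 5.48, 4.91 and 4.09, and other such genes were not counted. Hoxa11os, an antisense transcript of the HoxA cluster, decreased by 2.74 (SE 0.15, adjusted p = 3.897e-05), alongside Hoxa11. In the HoxB cluster 3 of 8 measured genes were lower and 1 higher, in HoxC 5 of 9 lower and 0 higher, and in HoxD 3 of 5 lower and 1 higher. The cyclin gene Ccnd1 decreased by 1.23 (SE 0.31, adjusted p = 0.02981).

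The muscle differentiation list, and with it the smooth muscle and fibroblast marker lists, was higher in both groups in the arrays numbered 3 and 4 than in those numbered 1 and 2. The mean of the differentiation list in replicates 1 and 2 was -0.41 and -0.56 in the eGFP arrays and 0.09 and 0.14 in the Hoxa9 arrays, and in replicates 3 and 4 it was 0.36 and 0.60, and 0.87 and 1.09. Within same-numbered pairs the Hoxa9 array was higher in 4 of 4, by 0.49 to 0.70, whereas the slides, which mix the numbers, gave differences of both signs. An exact sign-flip test of the 4 pairs gave p = 0.125, two-sided, the smallest that 4 pairs allow. The cell cycle list was lower in the Hoxa9 array of all 4 pairs, by a log2 difference of -1.77 to -0.99, and the interferon list higher in all 4, by 0.57 to 0.77, each with the same exact p of 0.125.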
